A study of Mus musculus with 13 samples.

How the data were processed

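The series holds bulk RNA sequencing of perivascular adipose tissue, the fat that surrounds blood vessels, from mice that received splenocytes. Per the labels, the donors were wild-type mice (WTS-R, 3 libraries), Nlrp3 knockout mice (NS-R, 3 libraries), mice with type 2 diabetes (TS-R, 4 libraries) or diabetic Nlrp3 knockout mice (NTS-R, 3 libraries). The genotype label of each sample does not say whether it describes the donor or the recipient, and groups follow the sample titles. The labels' protocols name TRIzol extraction, a check of RNA integrity and paired-end libraries from an ABclonal mRNA-seq kit. The labels give no batch, date, time of collection, age or sex. Nothing in the labels says which samples came from separate animals, so the p-values measure the spread between these samples.

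The deposited table holds counts per gene, as whole numbers, with 1 column per library. Per the submitters' processing notes the authors used HISAT2 and featureCounts, without versions; the genome build, annotation release and strand setting are not given in the sources used here. The table has 34013 genes, of which 33302 were matched to a symbol by identifier and 711 were not; 21 symbols were shared by more than 1 identifier. Libraries held from 14216706 counts (NTS-R replicate 3) to 37011122 counts (NS-R replicate 1). A count of 0 allows up to 3 counts, which is 0.081 CPM (counts scaled to library size) in NS-R replicate 1 and 0.211 CPM in NTS-R replicate 3. These floors cover counting error alone. Counts of immunoglobulin, haemoglobin and heat shock genes include reads that related genes can share, so their levels are less certain than those of other genes. No libraries of a group matched within sampling noise (the lowest chi-square per degree of freedom of any pair was 36.0).

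Differences between groups were tested with edgeR 4.0.16 in R 4.3.3. All 13 libraries entered a single quasi-likelihood fit with TMM normalization after filterByExpr, which left 17270 genes. Genes were called at a Benjamini-Hochberg FDR under 0.05. The comparisons were TS-R against WTS-R, NTS-R against TS-R, NS-R against WTS-R, NTS-R against NS-R, and the interaction, which is the donor diabetes effect under donor Nlrp3 knockout (NTS-R minus NS-R) less the same effect with wild-type donors (TS-R minus WTS-R). The spread between libraries was wide: the common biological coefficient of variation was 0.389 and the prior degrees of freedom 3.5. Fold changes are edgeR's fitted log2 values with their standard error (SE). CPM values are given as mean ± SD.

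There were 31 gene lists of cell types and processes. Of these, 29 were tested with camera at a preset correlation of 0.01, with adjustment over the lists of a comparison. The thymocyte list had 4 tested members, under the minimum of 5, and the sex-linked list was read without a test. Camera was repeated with an estimated correlation between members, and for each list the number of members past an FDR of 0.05 adjusted over the list alone was counted. Ccr6, a member of the T helper and regulatory list, had no counts in WTS-R; with that gene at the bound that 3 counts over the group allow, the list's median in TS-R against WTS-R was still 2.84, and in NS-R against WTS-R it was 0.22 in place of 0.33. List levels per library are means of log2(CPM + 0.5).

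Genes were named by a rule. It takes Nlrp3; then the genes with the largest fitted changes among those past the test, with groups that do not overlap and a mean CPM of 1 or more; where none passed, the 3 genes per direction with the smallest unadjusted p. It adds up to 4 members per list called by camera, and per list for the inflammasome, macrophage, T cell, B cell and brown adipocyte lists. The comparisons, tests, lists, naming rule and a first set of other settings were fixed before the data were examined. From the names the rule gives, those printed were picked after their values were seen, and marker genes given per library (such as Igha, Scgb1a1, Glycam1 and Xist) were also chosen then.

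The pipeline was tested on simulated data with the dispersions of these libraries. In each comparison 200 genes were changed, drawn from genes with a mean over 2 CPM. The recovery rates therefore do not cover weaker genes such as Nlrp3. A 4-fold change was recovered for 75% of genes in TS-R against WTS-R and 77% in NTS-R against TS-R. The share was 59% in NS-R against WTS-R and 66% in NTS-R against NS-R. A 2-fold change was recovered for 8%, 13%, 7% and 2% of genes. With the dispersions found without TS-R replicate 3 these were 84%, 77%, 80% and 80% for a 4-fold change and 33%, 39%, 18% and 18% for a 2-fold change. Simulated genes varied independently, with the same dispersion in every group, unlike libraries of uneven tissue content. A lack of edgeR calls in the real data therefore does not show that such changes were absent.

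The other settings fixed beforehand were DESeq2 1.42.0, limma 3.58.1 with voomWithQualityWeights, DESeq2 size factors (RLE) in edgeR, no filter on low counts, only the 2 groups compared, the replicate number as a block, an added requirement of an absolute log2 fold change of 1 or more, and each library left out in turn. After the data were seen, these were added: robust empirical Bayes, sex of the library as a covariate, male libraries only, depth class as a covariate (NS-R replicate 1 and TS-R replicates 1 and 3 against the others), mitochondrially encoded genes left out, and the clock gene level as a covariate. That level is the mean log2 level of 8 genes of the Dbp arm of the circadian clock minus that of 3 genes of the Arntl arm. The only female libraries were NS-R replicate 3 and TS-R replicate 3, so the sex covariate also takes up their tissue content. Fits on libraries chosen by their tissue content were set aside, because they would compare samples picked by a measured outcome. Python 3.11.15 with matplotlib 3.10.9 drew the plots.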

Results

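Perivascular fat holds brown-like adipocytes, vessel wall cells, nerves and resident immune cells. The series asks how splenocytes from diabetic donors, with or without donor Nlrp3, act on this tissue in the recipient. Nlrp3 encodes the sensor of an inflammasome that matures IL-1 beta. The 13 libraries differed widely in tissue content, also within groups. TS-R replicate 3 was rich in lymphoid transcripts. Glycam1, made by high endothelial venules of lymph nodes, was at 1166 CPM in TS-R replicate 3, 74.3 CPM in replicate 2, 8.54 CPM in replicate 4 and 0.0336 CPM in replicate 1, which is under the 3-count floor. TS-R replicate 1 was rich in skeletal muscle transcripts, with the fast myosin Myh4 at 3227 CPM. NS-R replicates 1 and 2 held airway transcripts. The club cell gene Scgb1a1 reached 2324 and 4629 CPM there and was at 0 in NS-R replicate 3. Xist marked NS-R replicate 3 (459.5 CPM) and TS-R replicate 3 (805 CPM) as female, and the other 11 libraries expressed Y-linked genes.

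**Figure D1:**
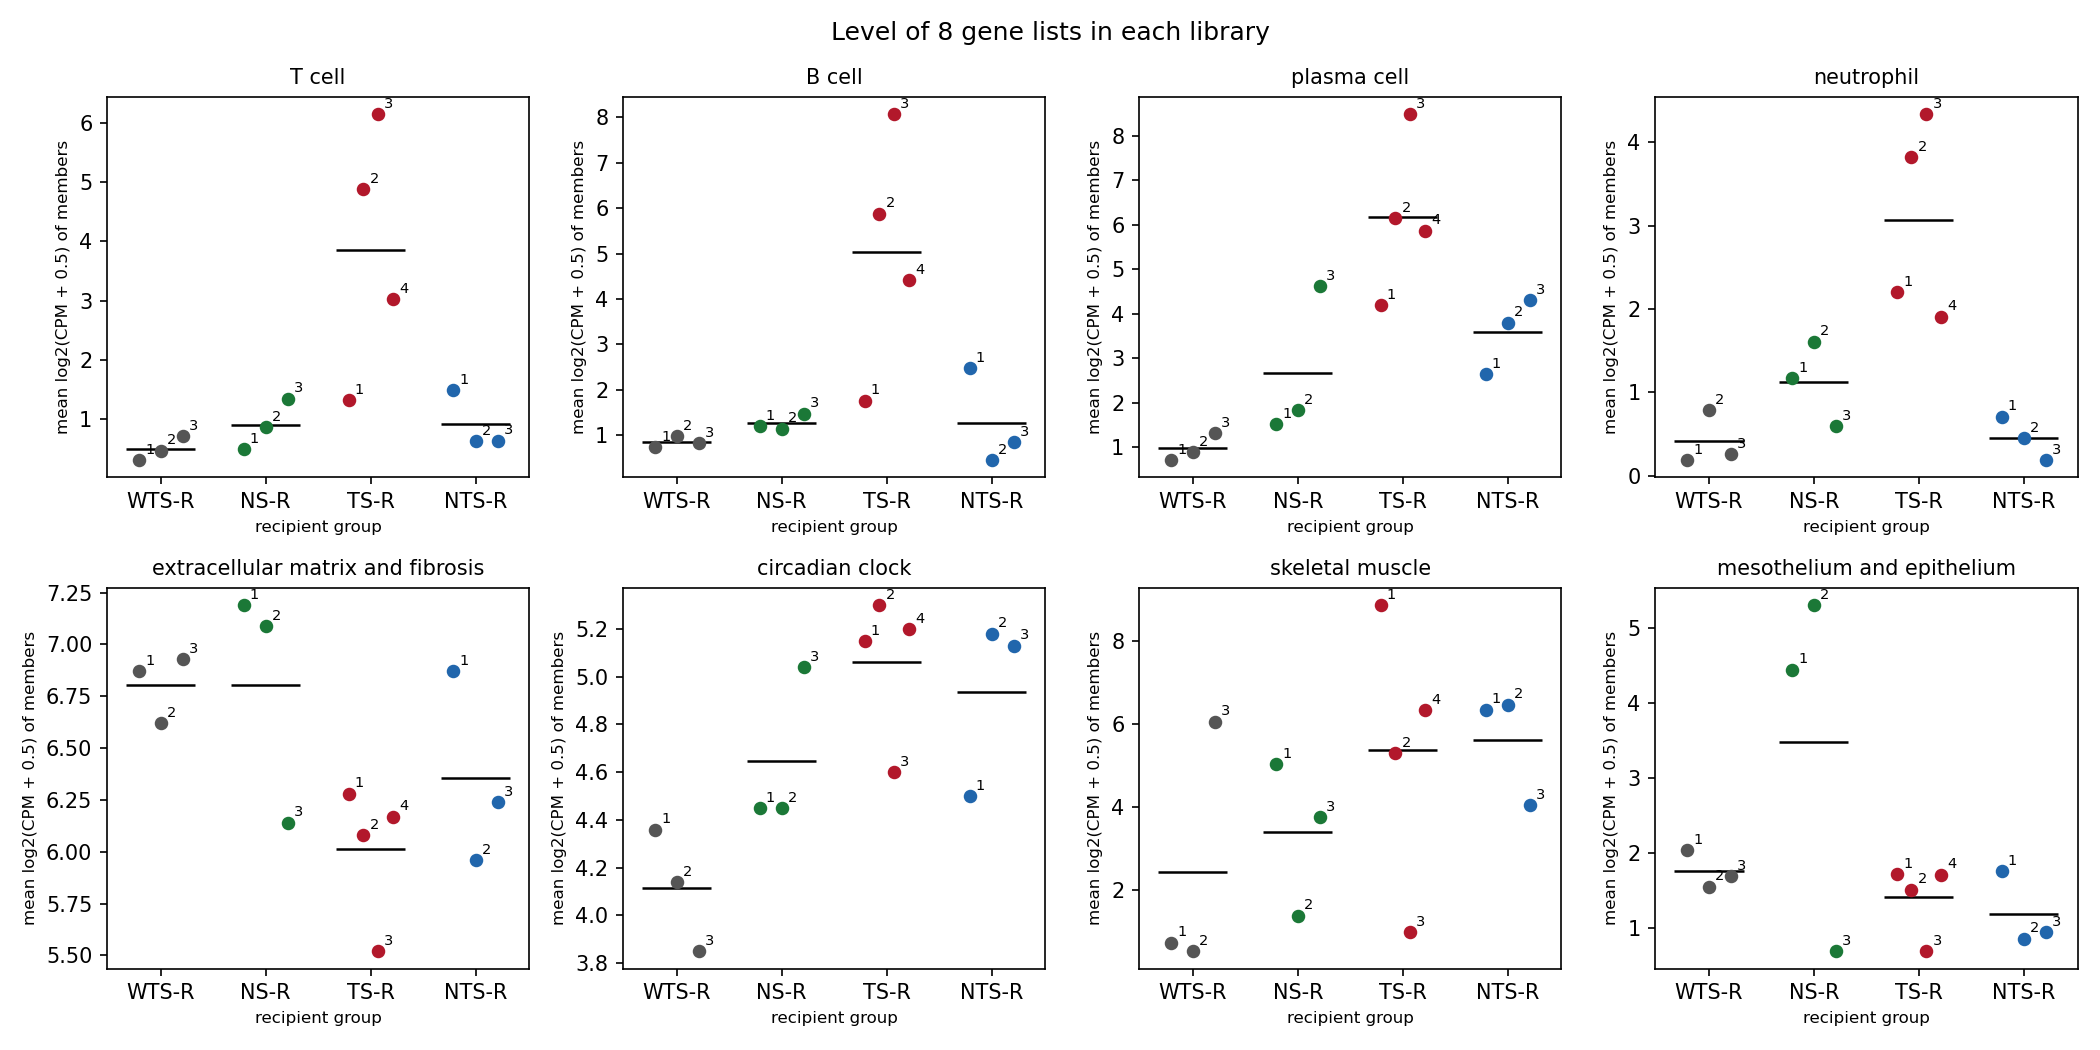
Mean log2(CPM + 0.5) of the members of 8 gene lists in each library, by recipient group; points are libraries with their replicate number and bars are group means. The T cell level was 6.16 in TS-R replicate 3 and 1.32 in TS-R replicate 1, against 0.30, 0.46 and 0.70 in WTS-R.

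Circadian clock genes, plasma cell genes and matrix genes separated libraries of a single group. The clock gene level (Dbp arm minus Arntl arm, log2) was 0.65, -0.32 and -0.70 in WTS-R and 3.32, 3.42, 1.70 and 3.48 in TS-R. In NS-R it was 0.23, 0.67 and 3.12, and in NTS-R 0.84, 4.32 and 3.38. The IgA heavy chain transcript Igha followed the same libraries. It was at 0.661, 3.16 and 8.45 CPM in WTS-R, 1.73, 7.69 and 460.6 CPM in NS-R, 490.4, 1148, 2296 and 1892 CPM in TS-R, and 4.52, 305.6 and 324.8 CPM in NTS-R. NS-R replicate 3 and NTS-R replicates 2 and 3 thus lay with TS-R for these genes. All 4 TS-R libraries had a higher clock gene level than all 3 WTS-R libraries, so this difference and the donor difference cannot be separated in that comparison. The labels name no batch that would explain it. The collagen Col3a1, a main fibre of loose connective tissue, was at 902, 722 and 906 CPM in WTS-R and 1177, 1155 and 267 CPM in NS-R. It was at 361.5, 261, 149 and 322 CPM in TS-R and 768, 269.5 and 382 CPM in NTS-R.

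Nlrp3 itself was near the detection limit and was not lower in NS-R than in WTS-R. It was at 0.507 ± 0.248 CPM in WTS-R (n = 3), 0.947 ± 0.456 CPM in NS-R (n = 3), 1.65 ± 1.31 CPM in TS-R (n = 4) and 0.684 ± 0.467 CPM in NTS-R (n = 3). Nlrp3 in TS-R replicate 3 was 3.55 CPM, and the other TS-R libraries had 0.537, 1.35 and 1.16 CPM. The edgeR log2 fold change of Nlrp3 was 1.42 (SE 0.68, FDR 0.240) in TS-R against WTS-R and -0.97 (SE 0.66, FDR 0.442) in NTS-R against TS-R. Nlrp3 gave 0.90 (SE 0.71, FDR 0.9997) in NS-R against WTS-R and -0.45 (SE 0.70, FDR 0.999) in NTS-R against NS-R. The Nlrp3 value in NTS-R against NS-R was 0.08 with sex as a covariate.

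**Figure D2:**
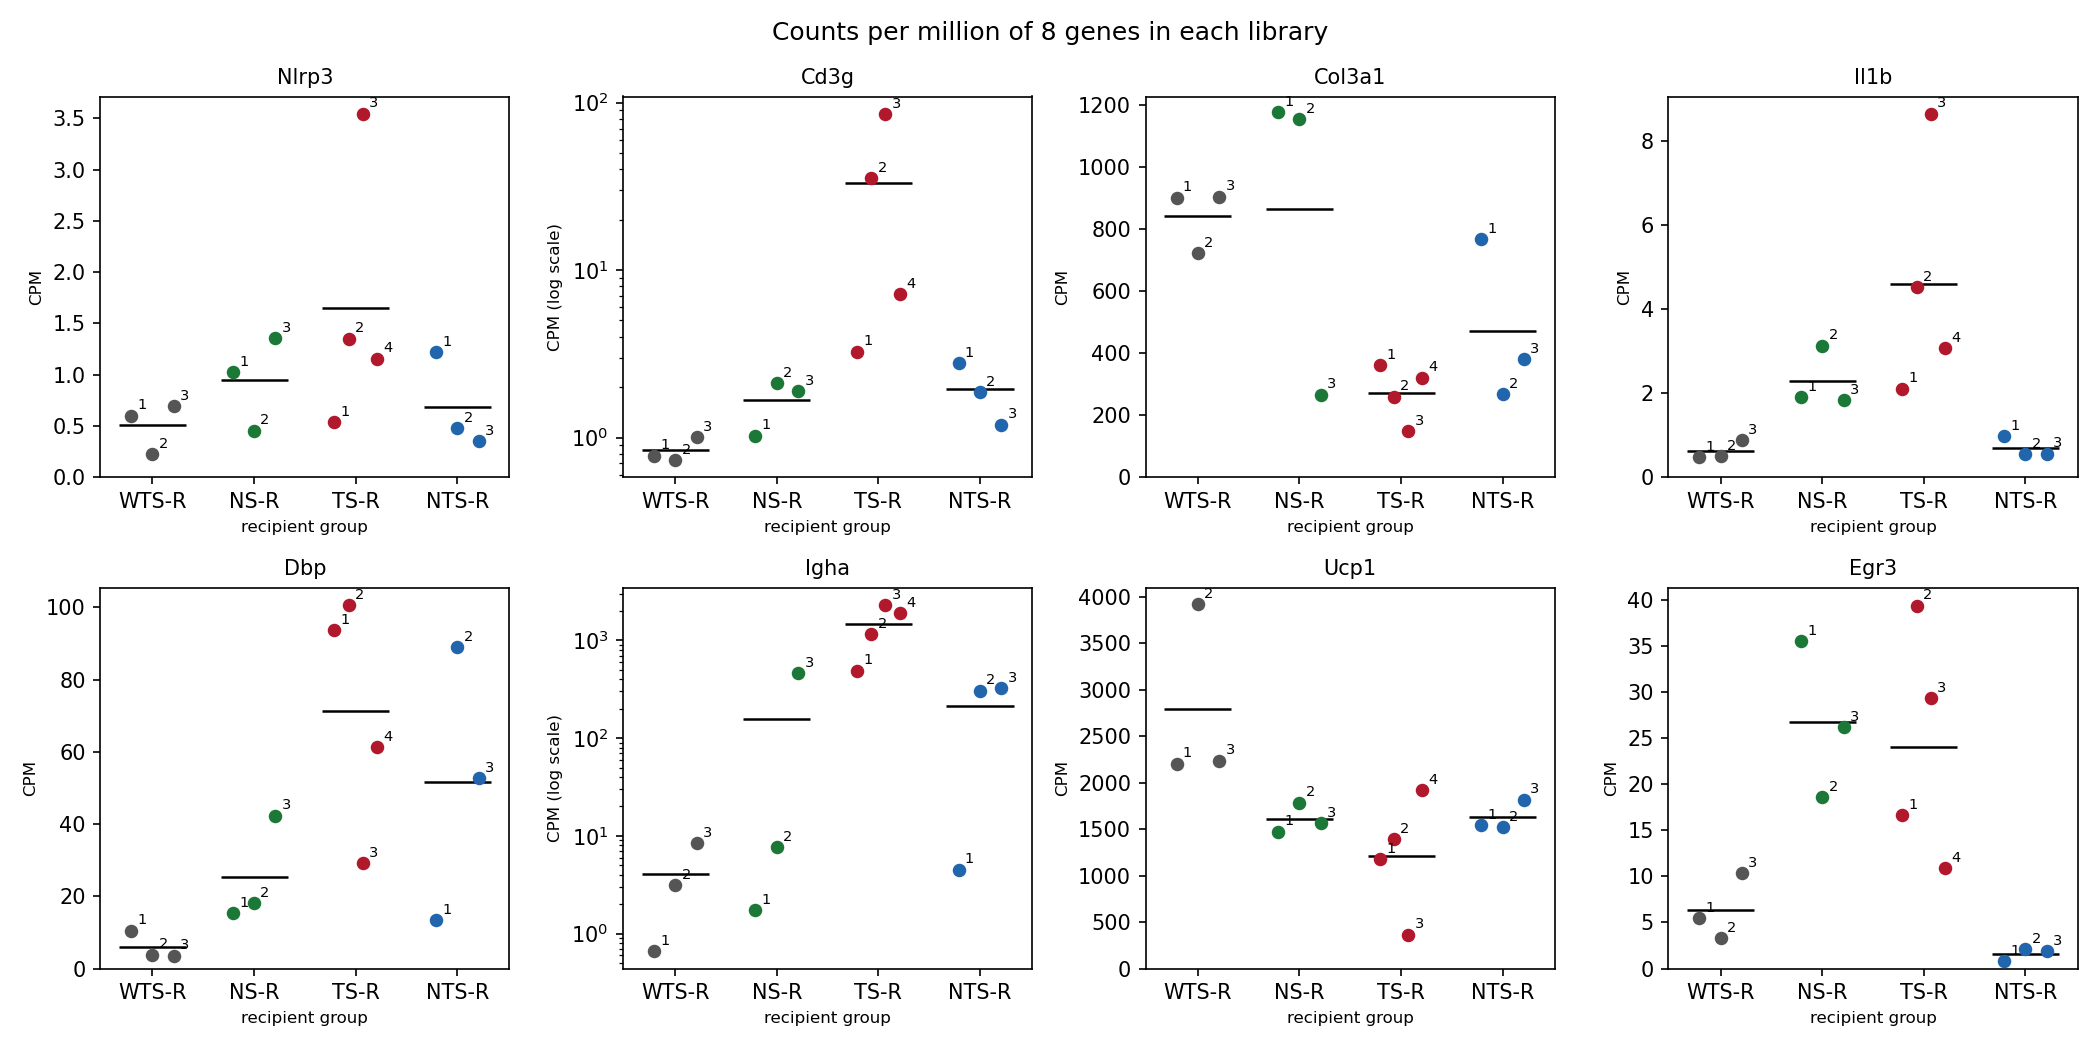
CPM of 8 genes in each library, by recipient group; points are libraries with their replicate number and bars are group means, with log axes for Cd3g and Igha. Egr3 lay between 0.812 and 2.14 CPM in the 3 NTS-R libraries, below the lowest library of each other group.

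The first question was what splenocytes of diabetic donors did to the fat, in TS-R against WTS-R. Lymphocyte genes lay far higher in TS-R. T cell genes such as Cd3g and Cd3d of the antigen receptor complex, and the signalling genes Zap70 and Lat, were many times above WTS-R. B cell genes (Blk, Cd79a, Pou2af1 and the IgM heavy chain Ighm) and plasma cell genes (Jchain and Prdm1) did the same. Neutrophil genes S100a8 and S100a9 were also higher, as were Siglech and Ciita of the dendritic cell and MHC class II list. These genes were highest in TS-R replicate 3, and Cd4 in TS-R replicate 1 (1.01 CPM) was no higher than in WTS-R. By edgeR 0 genes passed an FDR of 0.05 in either direction. At an unadjusted p under 0.05 there were 2622 genes higher and 1221 lower, with 864 in all given by chance, and the lowest FDR was 0.0624. DESeq2 called 1631 genes higher and 307 lower, and voomWithQualityWeights 2332 and 1484. Without TS-R replicate 1 edgeR called 1543 genes higher and 363 lower, and without TS-R replicate 4 984 and 254. With no filter on low counts it called 824 and 65, and with the clock gene level as a covariate 529 and 14.

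**Figure D3:**
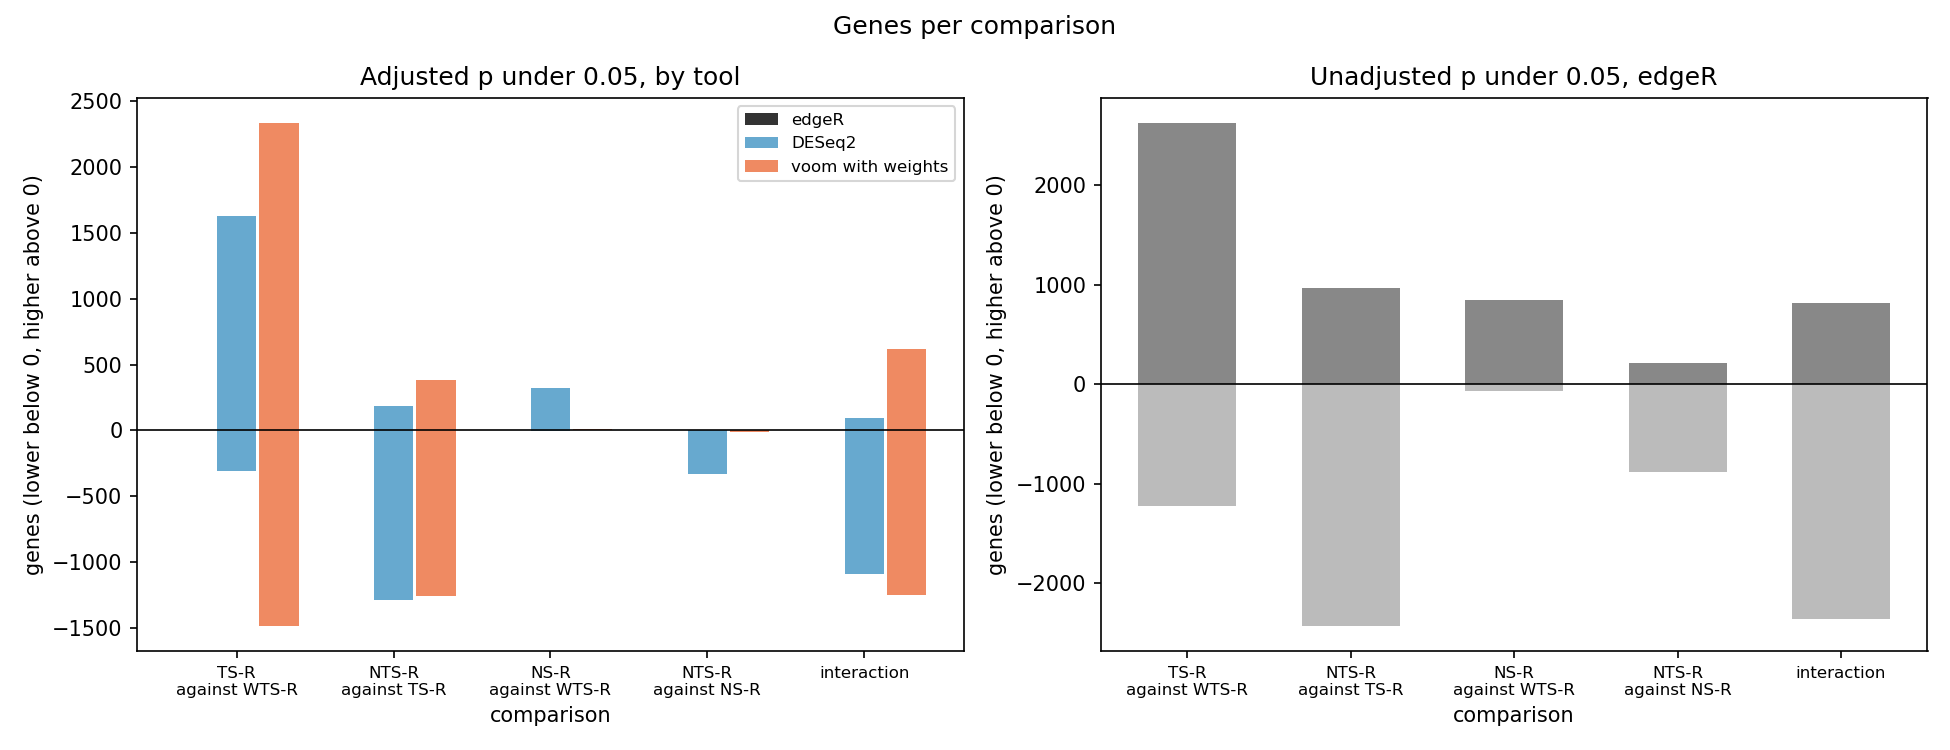
Number of genes per comparison, higher above 0 and lower below 0; the left panel gives genes at an adjusted p under 0.05 by edgeR, DESeq2 and voomWithQualityWeights, and the right panel genes at an unadjusted p under 0.05 by edgeR. edgeR gave 0 adjusted calls in every comparison, while DESeq2 called 1631 genes higher in TS-R than in WTS-R.

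Cd3g was at 32.9 ± 38.0 CPM in TS-R (n = 4) and 0.841 ± 0.147 CPM in WTS-R (n = 3), with a log2 fold change of 4.97 (SE 0.99, edgeR FDR 0.0624, DESeq2 adjusted p 2.04e-07). All 4 TS-R libraries were above all 3 WTS-R libraries for Cd3g. The median of the T cell list was 4.80, and 20 of 20 members were higher when adjusted over the list alone (camera adjusted p = 1.5e-17; adjusted p = 0.250 with an estimated correlation). The B cell list had a median of 6.03 with 16 of 16 members (camera adjusted p = 7.48e-14; 0.250 with an estimated correlation). Ighm was at 571 ± 504 CPM in TS-R (n = 4) and 25.5 ± 8.06 CPM in WTS-R (n = 3). The plasma cell list had a median of 7.01 with 12 of 14 members (camera adjusted p = 5.42e-12; 0.250 with an estimated correlation). Jchain, which joins IgA and IgM units, was at 857 ± 913 CPM in TS-R and 2.19 ± 0.680 CPM in WTS-R, but also at 179 CPM in NS-R replicate 3. The neutrophil list had a median of 4.27 with 10 of 12 members (0.250 with an estimated correlation). S100a9, a calcium-binding alarmin subunit, gave 4.70 (SE 0.72, edgeR FDR 0.0624). The dendritic cell and MHC class II list had a median of 1.84 with 14 of 16 members (0.250 with an estimated correlation). T helper and regulatory genes had a median of 2.84 with 9 of 12 members (0.250), and NK and cytotoxic genes 2.71 with 10 of 12 (0.285). These 2 medians were 1.84 and 1.74 without TS-R replicate 3. Without TS-R replicate 3 the median over T cell and B cell list members together was 3.99, and among male libraries 4.03, against 5.06 with every library.

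The inflammasome list was called higher with a smaller median, and the macrophage list had a median near 0. Il1b, the main inflammasome product, was at 4.60 ± 2.89 CPM in TS-R (n = 4) and 0.624 ± 0.224 CPM in WTS-R (n = 3), a log2 fold change of 2.59 (SE 0.50, edgeR FDR 0.0624). The DNA sensor Aim2 gave 3.28 (SE 0.75, edgeR FDR 0.0624), the IL-18 receptor chain Il18rap 3.03 and the adaptor Pycard 1.81. The inflammasome and IL-1 list had a median of 1.03, and 7 of 16 members were higher when adjusted over the list alone (camera adjusted p = 9.72e-06; adjusted p = 0.392 with an estimated correlation). The inflammasome median was 0.62 without TS-R replicate 3, 0.65 among male libraries and 1.77 with the clock gene level as a covariate. Lymphoid tissue also expresses Aim2 and Il18rap, and the highest library for Il1b was TS-R replicate 3 at 8.66 CPM. The macrophage and monocyte list had a median of 0.25 with 2 of 18 members (camera adjusted p = 0.0213; 0.504 with an estimated correlation). The macrophage call was lost without WTS-R replicate 2 (median 0.09) and among male libraries (0.26). It was 0.15 without WTS-R replicate 1, 0.70 without WTS-R replicate 3, 0.38 without TS-R replicate 1 and 0.78 with the clock covariate. Its receptor gene Csf1r gave 1.16 (edgeR FDR 0.0778) and the chemokine receptor gene Ccr2 1.09 (edgeR FDR 0.0667). The cytokine and chemokine list had a median of 0.53 (0.5002 with an estimated correlation), led by the lymphoid chemokines Cxcl13 at 4.74 and Ccl19 at 4.74. The cytokine call was lost without WTS-R replicate 2 (0.55) and among male libraries (0.38), and the median was 0.95 without WTS-R replicate 3 and 0.27 without TS-R replicate 3. Tnf gave 1.81 (SE 0.54, edgeR FDR 0.0843). Cell cycle genes had a median of 2.81 with 15 of 16 members (0.392 with an estimated correlation), and Mki67 was at 254.5 CPM in TS-R replicate 3 and between 14.7 and 33.3 CPM in the other TS-R libraries. The cell cycle median was 1.24 without TS-R replicate 3.

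Matrix genes lay lower in TS-R than in WTS-R, and adipocyte lists had negative medians that were nearer 0 without TS-R replicate 3. The matrix and fibrosis list had a median of -1.11, with 20 of 20 members negative and 15 of 20 lower when adjusted over the list alone (camera adjusted p = 4.3e-16; adjusted p = 0.250 with an estimated correlation). Col3a1 gave -1.89 (SE 0.46, edgeR FDR 0.0624), the collagen cross-linker Loxl2 -1.37 and the matricellular gene Postn -0.84. With the clock gene level as a covariate the median of the matrix list was -0.62. The brown adipocyte list had a median of -0.74, with 19 of 19 members negative and 0 of 19 past the test when adjusted over the list alone (camera adjusted p = 2.39e-07; 0.285 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, was at 1214 ± 645 CPM in TS-R (n = 4) and 2789 ± 981 CPM in WTS-R (n = 3), a log2 fold change of -1.46 (SE 0.46, edgeR FDR 0.0946). TS-R replicate 3 had 366 CPM of Ucp1 and 438.5 CPM of the adipokine gene Adipoq, the lowest of the 4 TS-R libraries for both. The median of the brown adipocyte list was -0.47 without TS-R replicate 3, -0.44 among male libraries and -1.39 with the clock gene level as a covariate. The respiratory chain list had a median of -0.59 (0.406 with an estimated correlation), fatty acid oxidation -0.65 (0.406) and adipocyte identity -0.49 (0.504). Without TS-R replicate 3 the respiratory chain median was -0.33, fatty acid oxidation -0.36 and adipocyte identity -0.19, and the call of adipocyte identity was lost. Its level was 10.1, 9.52, 8.17 and 9.76 in TS-R and 9.64, 9.66 and 9.61 in WTS-R. With the clock covariate they were -1.06, -1.15 and -0.99. Lep, the leptin gene, was at 344 CPM in TS-R replicate 1 and between 24.8 and 69.5 CPM in the other TS-R libraries.

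Clock and tissue content lists completed the comparison of TS-R with WTS-R. The clock list had a median of 1.03, with 7 members higher and 2 lower of 15 when adjusted over the list alone (0.442 with an estimated correlation). Dbp gave 3.30, Per3 2.26 and Bhlhe41 2.44, against -2.66 for Npas2, a gene of the Arntl arm. The clock list call was lost without WTS-R replicate 3 (median 0.74), TS-R replicate 1 (1.04) or TS-R replicate 4 (0.85). The interferon list had a median of -1.47 (0.568 with an estimated correlation), which rested on WTS-R replicate 1: without it the median was 0.13. Isg15 was at 210 CPM in WTS-R replicate 1 and at 10.9 and 28.4 CPM in replicates 2 and 3. Skeletal muscle genes had a median of 2.27 (0.568 with an estimated correlation), cardiac muscle -0.29 (0.568) and nerve and Schwann cell 1.31 (0.442). The skeletal muscle call was lost without TS-R replicate 1 (median 0.52), WTS-R replicate 1 (1.70) or WTS-R replicate 2 (1.69), and the median was 8.93 without WTS-R replicate 3. The cardiac call was lost without TS-R replicate 3 (-0.03) or WTS-R replicate 3 (0.06). Its median was -0.61 and -0.67 without WTS-R replicates 1 and 2, and -0.64 and -0.60 without TS-R replicates 1 and 4. The nerve call was lost without TS-R replicate 1 (1.15). Camera called 21 of 29 lists with the preset correlation and 0 with an estimated one. Lists not called were fatty acid and triglyceride synthesis at -0.28, vasoactive factors at -0.23, endothelium at -0.27, and mesothelium and epithelium at -1.04. The vascular smooth muscle list had a median of 0.04 and a mean of -0.08, and mast cell and eosinophil -0.39 and 0.43. Erythroid genes had a median of 0.20 and immediate early genes 0.27. Camera gave both the opposite direction but set neither apart from other genes (camera adjusted p = 0.981 and 0.9999).

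The next question was whether removing donor Nlrp3 altered the effect of diabetic splenocytes, in NTS-R against TS-R. The lymphocyte, neutrophil and cytokine genes that were high in TS-R were low in NTS-R. T cell genes Lat and Cd3d, B cell genes Ighd and Bank1 and the neutrophil genes S100a9 and S100a8 gave large negative values. Immediate early transcription factor Egr3 and the nerve growth factor receptor gene Ngfr were also lower. Brown fat regulators Ebf2 and Prdm16 and matrix genes had positive values. By edgeR 0 genes passed in either direction, with 966 higher and 2428 lower at an unadjusted p under 0.05 and a lowest FDR of 0.105. DESeq2 called 182 genes higher and 1286 lower, and voomWithQualityWeights 380 and 1258. Without TS-R replicate 1 edgeR called 37 and 981 genes, and without TS-R replicate 4 160 and 720. Both comparisons use the same TS-R libraries, so the tissue content of TS-R replicate 3 enters here as well.

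Lat was at 39.0 ± 43.2 CPM in TS-R (n = 4) and 1.60 ± 0.776 CPM in NTS-R (n = 3), with a log2 fold change of -4.29 (SE 0.96, edgeR FDR 0.105). The T cell list had a median of -3.93, and 20 of 20 members were lower when adjusted over the list alone (camera adjusted p = 6.99e-16; adjusted p = 0.355 with an estimated correlation). The B cell list had a median of -5.08 with 16 of 16 members (0.355 with an estimated correlation), and Ighd gave -5.67. The neutrophil list had a median of -4.07 with 11 of 12 members (0.355), and S100a9 gave -4.25 (SE 0.71, edgeR FDR 0.105). Plasma cell genes had a median of -3.19 with 5 of 14 members (0.355). Igha was at 305.6 and 324.8 CPM in NTS-R replicates 2 and 3, above every WTS-R library. Immunoglobulin genes share reads with their paralogs, so their single values are uncertain. The dendritic cell and MHC class II list had a median of -1.61 with 14 of 16 members (0.355). NK genes had -1.84 with 6 of 12 (0.355), and T helper genes -2.64 with 9 of 12 (0.355). The inflammasome list had a median of -0.99 with 6 of 16 members (0.355), and Il1b gave -2.40 (SE 0.49, edgeR FDR 0.105). Il1b was at 0.700 ± 0.247 CPM in NTS-R (n = 3), near its WTS-R level. Aim2 gave -3.02, Pycard -1.96 and Tnf -2.92. Macrophage and monocyte genes had a median of -0.53 with 2 of 18 members (0.379), and Cx3cr1 gave -1.84. Cytokine genes had a median of -0.52 (0.380) and cell cycle genes -2.50 with 15 of 16 members (0.355). Without TS-R replicate 3 medians were nearer 0: B cell -3.20, plasma cell -1.77, dendritic cell -1.03, NK -1.22, T helper -1.59, inflammasome -0.51, cytokines -0.34 and cell cycle -1.002. The macrophage median was -1.03 without NTS-R replicate 1 and -0.34 without NTS-R replicate 3. NK genes had -1.16 without NTS-R replicate 3, and cytokines -0.32 without TS-R replicate 2.

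Adipocyte, matrix, cardiac and smooth muscle lists had positive medians in NTS-R against TS-R. The brown adipocyte list had a median of 0.58 with 0 of 19 members past the test when adjusted over the list alone (camera adjusted p = 8.72e-07; adjusted p = 0.355 with an estimated correlation). Ebf2, which commits brown adipocyte precursors, gave 1.25 (SE 0.34, edgeR FDR 0.105), and Prdm16 gave 1.09. Adipocyte identity had a median of 0.54 (0.426), fatty acid oxidation 0.57 (0.376) and the respiratory chain list 0.33 (0.504). Without TS-R replicate 3 the medians were brown adipocyte 0.31, adipocyte identity 0.28, fatty acid oxidation 0.30 and respiratory chain 0.07, and the respiratory chain call was lost. Without TS-R replicate 4 brown adipocyte was 1.05 and adipocyte identity 0.82, and without TS-R replicate 1 the respiratory chain list was 0.51. The matrix list had a median of 0.66 with 4 of 20 members (0.355), and the growth factor gene Ccn2 gave 1.25. Cardiac muscle genes had a median of 1.35 with 6 of 12 members (0.355), with Sln at 1.70, and vascular smooth muscle 0.32 (0.379). The matrix median was 0.33 without NTS-R replicate 1, cardiac muscle 0.86 without NTS-R replicate 3 and vascular smooth muscle 0.74 without TS-R replicate 1. Nerve and Schwann cell genes had a median of -1.23 with 6 of 13 members (0.380), and lost the call without TS-R replicate 1 (-1.25). Ngfr was at 1.14 ± 0.260 CPM in NTS-R (n = 3) and at 24.97, 16.3, 13.5 and 1.93 CPM in TS-R. The skeletal muscle list had a median of -0.85. Camera gave it the opposite direction but did not set it apart from other genes (camera adjusted p = 0.614). Mesothelium and epithelium had a median of 0.08 and a mean of -0.64. Camera called 19 of 29 lists here and 0 with an estimated correlation. Egr3 gave -3.57 (SE 0.56, edgeR FDR 0.105), and the antioxidant gene Gpx8 1.41 (SE 0.24, edgeR FDR 0.105).

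The effect of donor Nlrp3 knockout without diabetes was read from NS-R against WTS-R. The immediate early gene Jun, which responds within minutes to stimuli and to tissue handling, was higher in all 3 NS-R libraries than in any WTS-R library. Junb, Zfp36 and Btg2 were high in NS-R replicates 1 and 2, and in replicate 3 (31.6, 92.6 and 62.9 CPM) lay below WTS-R replicate 3 (40.6, 94.3 and 86.1 CPM). The smooth muscle gene Myh11 was higher too, and Cnn1 was at 55.1 and 51.7 CPM in NS-R replicates 1 and 2 but at 14.5 CPM in replicate 3, under 1 WTS-R library (15.6 CPM). Epithelial genes Cdh1 and Epcam and the neutrophil and airway gene Ltf were high in NS-R replicates 1 and 2, which held airway transcripts. The T cell receptor gene Cd3g was at 1.03, 2.11 and 1.89 CPM in NS-R. By edgeR 0 genes passed, with 850 higher and 67 lower at an unadjusted p under 0.05 against 864 given by chance, and a lowest FDR of 0.204. DESeq2 called 319 genes higher and 1 lower, and voomWithQualityWeights 14 and 0. Without NS-R replicate 3, which left the libraries with airway transcripts, edgeR called 503 genes higher and 0 lower.

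Jun was at 225 ± 40.1 CPM in NS-R (n = 3) and 86.5 ± 36.3 CPM in WTS-R (n = 3), a log2 fold change of 1.35 (SE 0.31, edgeR FDR 0.204). The immediate early list had a median of 1.12, and 10 of 18 members were higher when adjusted over the list alone (camera adjusted p = 1.8e-12; adjusted p = 0.161 with an estimated correlation). Its level was 6.19 and 7.26 in NS-R replicates 1 and 2, which held airway transcripts, and 5.86 in replicate 3, against 5.28, 5.36 and 5.70 in WTS-R; the median was 0.73 without NS-R replicate 2. The vascular smooth muscle list had a median of 0.96 with 6 of 12 members (camera adjusted p = 4.65e-12; 0.161 with an estimated correlation). Its level was 5.49 and 4.70 in NS-R replicates 1 and 2, which held airway transcripts, and 4.39 in replicate 3, against 3.66, 3.66 and 4.50 in WTS-R. Without NS-R replicate 1 the median was 0.52. Myh11, the smooth muscle myosin, was at 215.5, 91.8 and 93.4 CPM in NS-R and 43.0, 41.2 and 54.5 CPM in WTS-R. Il1b gave 1.84 (SE 0.51, edgeR FDR 0.343), with 1.92, 3.14 and 1.83 CPM in NS-R and 0.481, 0.508 and 0.882 CPM in WTS-R. The inflammasome list had a median of 0.37 with 0 of 16 members (camera adjusted p = 0.0425; 0.806 with an estimated correlation). That call was lost without WTS-R replicate 1 (0.28) or 2 (0.28), or NS-R replicate 1 (0.19), 2 (0.39) or 3 (0.33). The prostaglandin synthase gene Ptgs2 gave 2.23 and was highest in NS-R replicates 1 and 2. Il6 was at 1.54 and 1.48 CPM there and at or under the 3-count floor in WTS-R, which gives no firm fold. Plasma cell genes had a median of 3.24 with 6 of 14 members (0.609 with an estimated correlation), which rested on NS-R replicate 3 (median 0.87 without it, not called): Ighg2c was at 247 CPM there and at 0.540 and 0.684 CPM in replicates 1 and 2.

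Epithelial genes were high in 2 of 3 NS-R libraries. Cdh1 was at 23.1 and 37.7 CPM in NS-R replicates 1 and 2 and at 0.0591 CPM, under the 3-count floor, in replicate 3. The mesothelium and epithelium list had a median of 1.17 with 2 of 10 members higher when adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.697 with an estimated correlation). The call was lost without NS-R replicate 1 (1.21) or 2 (0.44). The median was 2.98 without NS-R replicate 3, and 2.70, 2.14 and 2.46 without WTS-R replicates 1, 2 and 3. The T cell list had a median of 0.66 with 0 of 20 members (0.806); it was 0.14 without NS-R replicate 3, which had the highest Cd3e of the group at 2.01 CPM, and -0.07 with sex as a covariate. The T cell call was also lost without WTS-R replicate 1 (0.43), WTS-R replicate 2 (0.53) or NS-R replicate 2 (0.68). The B cell list was not called, with a median of 0.56. The interferon list had a median of -1.47 (0.697) and 0.17 without WTS-R replicate 1. Brown adipocyte genes had a median of -0.39 with 0 of 19 members (0.697), and Ucp1 was at 1608 ± 159 CPM (n = 3), with -0.84 (SE 0.50, edgeR FDR 0.9997). The respiratory chain list had a median of -0.41 (0.697), fatty acid oxidation -0.43 (0.697) and adipocyte identity -0.29 (0.806). With sex as a covariate the calls were lost: brown adipocyte -0.15, respiratory chain -0.10, fatty acid oxidation -0.05 and adipocyte identity 0.03. The sex term rests on NS-R replicate 3 and TS-R replicate 3, and the adipocyte identity level was 8.17 in the latter. These values therefore do not tell sex from the tissue content of TS-R replicate 3. The brown adipocyte call was lost without WTS-R replicate 2 (-0.23), and that of adipocyte identity without WTS-R replicate 2 (-0.25) or NS-R replicate 3 (-0.30). The clock list had a median of 0.86 (0.697), cytokines 0.33 (0.697), nerve 0.13 (0.697), cardiac muscle 0.58 (0.724) and neutrophil 0.38 (0.697). The clock call was lost without NS-R replicate 3 (0.28) or WTS-R replicate 3 (0.53). The cytokine call was lost without WTS-R replicate 1 (0.24) or 2 (0.20), or NS-R replicate 2 (0.21) or 3 (0.24), and was 0.52 without WTS-R replicate 3. The nerve call was lost without WTS-R replicate 1 (0.09) or 2 (0.10), or NS-R replicate 1 (0.14) or 3 (0.06), and was 1.15 without WTS-R replicate 3 and 0.39 without NS-R replicate 2. The cardiac call was lost without WTS-R replicate 1 (0.37) or 2 (0.30), or NS-R replicate 1 (0.42) or 3 (0.65), and was 1.09 without WTS-R replicate 3. The neutrophil call was lost without WTS-R replicate 1 (0.28) or 3 (0.35), or NS-R replicate 2 (0.18) or 3 (0.28), and was 1.60 without WTS-R replicate 2 and 0.60 without NS-R replicate 1. The macrophage list was not called, with a median of -0.12. Camera called 16 of 29 lists and 0 with an estimated correlation.

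Donor diabetes under donor Nlrp3 knockout was read from NTS-R against NS-R. Immediate early genes were lower in NTS-R, among them Jun, Nr4a1, Fosb and Egr3, and the kinase gene Sik1. The list level was 6.19 and 7.26 in NS-R replicates 1 and 2, which held airway transcripts, and 5.86 in replicate 3. In NTS-R it was 5.08, 5.19 and 5.34. Fos was at 131, 478 and 24.0 CPM in NS-R and 30.6, 19.1 and 35.1 CPM in NTS-R. Epithelial genes Cdh1, Epcam, Krt8 and Krt19 were lower too, and in NS-R they were high in the 2 libraries that held airway transcripts. The stress hormone target Fkbp5 was higher. Lymphocyte genes showed no such difference as in TS-R against WTS-R. By edgeR 0 genes passed, with 216 higher and 883 lower at an unadjusted p under 0.05 and a lowest FDR of 0.150. DESeq2 called 4 genes higher and 330 lower, and voomWithQualityWeights 0 and 12. Without NS-R replicate 3 edgeR called 7 and 556 genes.

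Nr4a1, an orphan nuclear receptor induced by activation, was at 54.2 ± 9.12 CPM in NTS-R (n = 3) and 510 ± 210 CPM in NS-R (n = 3), a log2 fold change of -3.15 (SE 0.52, edgeR FDR 0.150). Jun gave -1.97 (SE 0.31, edgeR FDR 0.150) and Egr3 -3.98 (SE 0.58, edgeR FDR 0.150). All 3 NTS-R libraries were below all 3 NS-R libraries for Jun, Nr4a1 and Egr3. The immediate early list had a median of -1.46, and 11 of 18 members were lower when adjusted over the list alone (camera adjusted p = 4.49e-19; adjusted p = 0.0541 with an estimated correlation). Fkbp5 was at 77.0 ± 27.8 CPM in NTS-R and 18.3 ± 2.66 CPM in NS-R, a log2 fold change of 2.11 (SE 0.35, edgeR FDR 0.150). The mesothelium and epithelium list had a median of -2.50 with 5 of 10 members (0.779 with an estimated correlation), and -1.66, -3.96 and -4.09 without NS-R replicate 2, NS-R replicate 3 and NTS-R replicate 1. Vascular smooth muscle genes had a median of -0.62 with 2 of 12 members (0.779), and Myh11 gave -1.17; the call was lost without NS-R replicate 1 (-0.23). The T cell list had a median of 0.19 and the B cell list 0.37, and neither was called. The inflammasome list was not called, with a median of -0.18, while Il1b gave -1.65 (SE 0.50, edgeR FDR 0.373). Macrophage genes at 0.19 and brown adipocyte genes at 0.08 were not called. Interferon genes had a median of 0.88 (0.832 with an estimated correlation) and -0.89 without NTS-R replicate 1, where Gbp2 was at 625 CPM against 43.5 and 42.1 CPM in the other NTS-R libraries. The interferon call was also lost without NS-R replicate 2 (0.67) or 3 (0.73). The matrix list had a median of -0.39 (0.779), the clock list 0.58 (0.779) and skeletal muscle 1.82 (0.779). Erythroid genes had a median of -1.42 (0.779), nerve genes -0.75 (0.779), cytokines -0.23 (0.779), endothelium -0.24 (0.832), fatty acid oxidation 0.31 (0.832) and adipocyte identity 0.30 (0.832). Most of these calls were lost with 1 library left out. Matrix lost it without NTS-R replicate 2 (-0.23), fatty acid oxidation without NS-R replicate 3 (0.29), and adipocyte identity without NS-R replicate 1 (0.27), NS-R replicate 3 (0.34) or NTS-R replicate 2 (0.24). Endothelium lost it without NS-R replicate 3 (-0.07), NTS-R replicate 1 (-0.15) or 2 (-0.26), and erythroid genes without NS-R replicate 2 (-0.65) or NTS-R replicate 3 (-1.05). Nerve genes lost it without NS-R replicate 1 (-0.39) or 3 (-0.25) or NTS-R replicate 3 (-0.64). Cytokines lost it without NS-R replicate 2 (-0.23) or 3 (-0.28) or NTS-R replicate 2 (-0.30) or 3 (-0.14), and were at -0.44 and -0.53 without NS-R replicate 1 and NTS-R replicate 1. Clock genes lost it without NS-R replicate 1 (0.40) or 2 (0.42) or NTS-R replicate 2 (0.44) or 3 (0.40), and were at 0.96 and 0.91 without NS-R replicate 3 and NTS-R replicate 1. Skeletal muscle was at 3.29 without NS-R replicate 1, and with sex as a covariate it lost the call (0.56). Camera called 13 of 29 lists and 0 with an estimated correlation.

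The interaction asks whether donor diabetes acted differently when donors lacked Nlrp3. Lymphocyte, neutrophil and inflammasome genes had negative values. Their lists were called higher in TS-R against WTS-R with the preset correlation, but not with an estimated one, and were not called in NTS-R against NS-R. Immediate early genes had negative values too. Their list was called lower in NTS-R against NS-R with the preset correlation (camera adjusted p = 0.0541 with an estimated one). It was not called in TS-R against WTS-R. The list level was highest in NS-R replicates 1 and 2 (6.19 and 7.26), which held airway transcripts, and 5.86 in NS-R replicate 3. Egr3 and Egr2, transcription factors of activated cells, gave the smallest p-values. Brown fat and respiratory genes had positive values. By edgeR 0 genes passed, with 812 higher and 2353 lower at an unadjusted p under 0.05 and a lowest FDR of 0.0823. DESeq2 called 98 genes higher and 1086 lower, and voomWithQualityWeights 621 and 1251. Without TS-R replicate 1 edgeR called 7 and 510, without NS-R replicate 3 3 and 295, and without TS-R replicate 4 8 and 63.

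Egr3 had an interaction value of -5.63 (SE 0.77, edgeR FDR 0.0823), and Egr2 -5.29 (SE 0.74, edgeR FDR 0.0823). Egr3 was at 6.36 ± 3.61 CPM in WTS-R (n = 3), 26.8 ± 8.48 CPM in NS-R (n = 3), 24.1 ± 12.8 CPM in TS-R (n = 4) and 1.62 ± 0.708 CPM in NTS-R (n = 3). Il1b gave -4.24 (SE 0.71, edgeR FDR 0.115) and Nlrp3 -1.87 (SE 0.97, edgeR FDR 0.328). Il18r1 gave -4.79 (SE 1.18, edgeR FDR 0.136); it was at 11.0 and 10.9 CPM in NS-R replicates 1 and 2, which held airway transcripts, and at 1.95 CPM in replicate 3, within the WTS-R range of 1.07 to 1.98 CPM. The inflammasome list had a median of -0.96, with 5 of 16 members lower when adjusted over the list alone (camera adjusted p = 2.26e-05; adjusted p = 0.374 with an estimated correlation). The inflammasome median was -0.64 without TS-R replicate 3, -1.47 and -1.65 without WTS-R replicates 1 and 3, -1.56 without NS-R replicate 2 and -1.57 without NTS-R replicate 1. The T cell list had a median of -4.65 with 20 of 20 members (0.374), the B cell list -5.58 with 16 of 16 (0.374) and the plasma cell list -6.88 with 13 of 14 (0.374), which was -4.26 without NS-R replicate 3. Neutrophil genes had a median of -4.79 with 10 of 12 members (0.374), and the immediate early list -1.94 with 10 of 18 (0.374). Among male libraries the T cell median was -3.08 and the immediate early median -2.07. The brown adipocyte list had a median of 0.89 with 0 of 19 members (0.374), and Ucp1 gave 1.53 (SE 0.68, edgeR FDR 0.254). The macrophage list was not called, with a median of -0.29. Camera called 19 of 29 lists and 0 with an estimated correlation.

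Donor diabetes effects in the 2 donor genotypes were compared across genes, which are not independent replicates. The log2 fold changes of TS-R against WTS-R and of NTS-R against NS-R had r = -0.102 and rho = -0.138 over 17270 genes. At an unadjusted p under 0.05 in both, 11 genes were higher in both (32.8 given by chance) and 34 lower in both (62.4). Without NS-R replicate 3 the r was 0.149. The share of the diabetes effect that lay opposite under donor knockout was read from genes higher in TS-R than in WTS-R and lower in NTS-R than in TS-R. By edgeR 0 genes were called in both. At an unadjusted p under 0.05, 1853 genes were higher then lower (368.6 given by chance), and 448 lower then higher (68.3). Shared TS-R libraries produce such a pattern on their own. Simulated unchanged groups gave means of 56.4 and 81.9 genes, with r = -0.401 and a covariance of -0.103. Here r was -0.839 and the covariance -1.23. Simulated genes varied independently, without the tissue content that moves many genes together in a library. The simulation therefore cannot say how much of r the shared libraries give here. With different TS-R libraries in each comparison, 2 and 2, r ran from -0.529 to -0.757 over 6 splits. In these splits 502 to 953 genes were higher then lower (176.1 to 263.8 given by chance), and 91 to 181 lower then higher (18.6 to 82.6). Each comparison held fewer TS-R libraries there. Cd3g was above every WTS-R library in all TS-R libraries, so both parts of a split carry lymphoid transcripts. Called genes numbered 909 without TS-R replicate 1 and 650 without TS-R replicate 4.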

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

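The tests in this part were chosen after the results were seen, except the interaction, which was fixed beforehand.

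In TS-R, the group of 4 libraries, 116 values were tested for 1 library far from the others, and 12 were found. Chance flags about 1 in 20 groups of normally distributed values. Most values tested were CPM, which are skewed, of genes named for their group differences, so that rate does not hold for them. TS-R replicate 3 stood apart for B cell genes Pou2af1 (352.2 CPM, next library 49.18) and Iglc2 (225 CPM, next 43.43) and the chemokine gene Cxcl13 (300.6 CPM, next 51.81). It also did for the cell division genes Top2a (200.7 CPM, next 26.11) and Mki67 (254.5 CPM, next 33.28). It was lowest for the respiratory gene Uqcrfs1 (191.5 CPM, next 473.3), the atrial muscle gene Myl7 (37.41 CPM, next 137.2) and the cardiac muscle list level (3.62, next 5.67). TS-R replicate 1 stood apart for Lep (344.2 CPM, next 69.47), Myh4 (3227 CPM, next 71.37) and Creg2 (1.51 CPM, next 2.762). TS-R replicate 4 did for the glycerol kinase gene Gk (97.32 CPM, next 26.15).

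Donor diabetes effects differed between donor genotypes for 19 lists by camera on the interaction, with the preset correlation. With an estimated correlation the adjusted p ran from 0.374 to 0.498 and 0 lists were called. Immune lists had negative medians: T cell -4.654, T helper and regulatory -2.925, B cell -5.575, plasma cell -6.881, neutrophil -4.791, NK and cytotoxic -2.419, dendritic cell -1.671, inflammasome -0.959 and cytokines -1.378. Nerve and Schwann cell at -2.057, cell cycle at -2.949 and immediate early genes at -1.94 were negative too. Positive medians were those of brown adipocyte 0.891, adipocyte identity 0.859, fatty acid oxidation 0.962, respiratory chain 0.722, interferon 2.221, matrix 0.627 and cardiac muscle genes 0.74. Without TS-R replicate 3 medians were T helper -1.90, NK -1.26, dendritic cell -0.95, inflammasome -0.64, cytokines -0.88, cell cycle -1.32 and respiratory chain 0.47. The inflammasome median was -1.47, -1.65, -1.56 and -1.57 without WTS-R replicate 1, WTS-R replicate 3, NS-R replicate 2 and NTS-R replicate 1. Plasma cell genes had -4.26 without NS-R replicate 3, and matrix genes 0.32 without NTS-R replicate 1. The interferon call was lost without WTS-R replicate 1 (0.64) or NTS-R replicate 1 (0.82), and the cardiac call without WTS-R replicate 3 (0.30), TS-R replicate 3 (0.47) or NTS-R replicate 3 (0.39).

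Lymphocyte genes were higher in TS-R than in WTS-R, with a median of 5.06 over T cell and B cell list members and 36 of 36 positive. Lymph node stroma and high endothelial venule genes had a median of 4.72 with 6 of 6 positive, and 2.52 over 5 genes without TS-R replicate 3. Lymph node tissue carried along in the dissection would give such values. Among these genes were Cxcl13 and Ccl19, which led the cytokine list above. The test was therefore not independent of values already seen. Replicate 3 alone does not account for the pattern (median without it 3.99). Among male libraries the median was 4.026, but replicate 3 was the only female library of TS-R and WTS-R. Both checks thus keep the same libraries of these groups, and sex cannot be told from the tissue content of replicate 3. Within TS-R the T cell list level had the same order as Glycam1. The level was 1.32, 4.89, 6.16 and 3.02 in replicates 1 to 4, and Glycam1 was at 0.0336, 74.3, 1166 and 8.54 CPM. The level in replicate 1, where Glycam1 was under the floor, was above WTS-R (0.30, 0.46 and 0.70) but under NTS-R replicate 1 (1.48). Lymphoid clusters that form within fat express the same stroma genes, so the stroma gene test does not tell them from a lymph node. An effect of the diabetic donors on lymphocytes in the tissue therefore stays open.

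Clock genes lay apart between TS-R and WTS-R, with a median of 1.35 for the Dbp arm (8 of 8 positive) and -1.473 for the Arntl arm (0 of 3 positive). Opposite movement of the arms is what a different time of day at collection would give, but these values were known before the test was written, and no collection times are in the labels. The difference also ran within groups: the clock gene level was 0.23, 0.67 and 3.12 in NS-R and 0.84, 4.32 and 3.38 in NTS-R. Against the donor as the sole cause stands this spread within groups of a single donor type. An effect of diabetic splenocytes on the clock stays open for TS-R.

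Airway genes appeared in NS-R replicates 1 and 2. Over 8 ciliated cell genes the median log2 ratio to NS-R replicate 3 was 2.98 in replicate 1 and 3.94 in replicate 2, which is consistent with airway tissue carried along in the dissection. Cartilage genes, which a piece of trachea or bronchus would bring, were weak and had median log2 ratios of 0.41 and 0.24. All these ratios had 0.5 CPM added on both sides, which draws those of weak genes toward 0. However, Col2a1 was at 1.62 CPM and Acan at 1.49 CPM in NS-R replicate 1, against 0.0591 and 0 CPM in replicate 3. Which part of the airway was present stays open.

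The same libraries were regrouped, in every other way for pairs of groups and in 99 random draws for the interaction. In TS-R against WTS-R chance cannot be excluded: 3 of 35 splits gave as many genes at an unadjusted p under 0.05 (3843, highest other 5200) and 8 of 35 as many called lists (21, highest other 23). In NTS-R against TS-R it cannot either: 5 of 35 for unadjusted p (3394, highest other 4609) and 19 of 35 for lists (19, highest other 25). NS-R against WTS-R and NTS-R against NS-R have 10 splits each, too few for a share under 0.05. In NS-R against WTS-R, 3 gave as many genes at an unadjusted p (917, highest other 1236) and 1 as many lists (16, highest other 15). In NTS-R against NS-R these were 2 (1099, highest other 1324) and 5 (13, highest other 19). For the interaction, 2 of 100 gave as many genes at an unadjusted p, the real grouping included (3165, highest other 4587). For lists these were 35 of 100 (19, highest other 25). The draws moved libraries between all groups, so they ask whether any group differed. They cannot exclude chance for the interaction by itself.

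At FDR under 0.05 edgeR called 0 genes in each real grouping, so 35 of 35, 35 of 35, 10 of 10, 10 of 10 and 100 of 100 splits gave as many by construction, and this says nothing about chance. The highest counts in other splits were 2244 (TS-R against WTS-R), 1265 (NTS-R against TS-R), 0 (NS-R against WTS-R), 0 (NTS-R against NS-R) and 805 (interaction). Moving TS-R replicate 1 or 4 to the WTS-R side called 2244 and 424 genes, and moving either to the NTS-R side 1265 and 992. What gave such counts was not tested. At an unadjusted p under 0.05 the real groupings gave 3843, 3394, 917, 1099 and 3165 genes, DESeq2 called 1631 higher and 307 lower, 182 and 1286, 319 and 1, 4 and 330, and 98 and 1086, and voomWithQualityWeights 2332 and 1484, 380 and 1258, 14 and 0, 0 and 12, and 621 and 1251.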

How the results depend on the processing

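Sex as a covariate, male libraries alone, depth class, the clock gene level, robust empirical Bayes and leaving out mitochondrial genes were chosen after seeing the data. edgeR called 0 genes in every comparison, and this stayed so with RLE size factors, robust empirical Bayes, depth class and mitochondrial genes left out. An added fold-change minimum can only take calls away, so it gave 0 by construction. Counts below are higher and lower genes, in the order TS-R against WTS-R, NTS-R against TS-R, NS-R against WTS-R, NTS-R against NS-R and interaction. DESeq2: 1631 and 307, 182 and 1286, 319 and 1, 4 and 330, 98 and 1086. voomWithQualityWeights: 2332 and 1484, 380 and 1258, 14 and 0, 0 and 12, 621 and 1251. No low-count filter: 824 and 65, 16 and 388, 137 and 1, 1 and 125, 1 and 91. With only the 2 groups compared, 1 and 4 in NTS-R against NS-R and 0 in the other comparisons. Sex covariate: 17 and 1, 0 and 0, 101 and 0, 1 and 131, 0 and 21. Male libraries: 49 and 1, 0 and 0, 674 and 0, 33 and 725, 5 and 396. Clock gene level: 529 and 14, 0 and 0, 18 and 0, 0 and 0, 0 and 109. Leaving out 1 library gave 0 to 1543 and 0 to 363, 0 to 160 and 0 to 981, 0 to 503 and 0 to 0, 0 to 7 and 0 to 556, 0 to 8 and 0 to 510. The cause was not tested.

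With a replicate block the counts were 619 and 165, 11 and 65, 0 and 0, 0 and 0, 2 and 17, and 71 genes lay opposite. Whether equal numbers pair the samples is not known. Of 18 same-number pairs 6 had r over 0.1, with r from -0.258 to 0.268. Their mean r was 0.021, against -0.008 for other pairs, and 5 of 13 libraries correlated best with their own number. These values show no clear pairing but cannot exclude it.

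Camera called 88 lists over the comparisons and 0 with an estimated correlation; the other settings gave 78 to 97, and leaving out 1 library 81 to 96. Genes opposite under donor knockout were 0, against 329 with no low-count filter and 0 to 909 with 1 library left out. The correlation of donor diabetes effects was -0.102 and ran from -0.184 to 0.149 with 1 library left out. It was 0.154 with sex as a covariate, 0.164 in male libraries, and -0.004 with depth class and with the clock gene level. The cause was not tested.

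Called lists kept direction and threshold in 879 of the values under settings fixed beforehand, lost the call in 170 and turned in 4; under later settings these were 472, 51 and 5. No named gene was past the threshold in the main fit. Under settings fixed beforehand they kept direction and were again not past it in 2232 values, passed it in 670 and turned in 4. Under later settings these were 1178, 123 and 1. With 1 library left out the interferon list ran from -1.955 to 0.127 in TS-R against WTS-R and from -1.93 to 0.174 in NS-R against WTS-R, each highest without WTS-R replicate 1, and from -0.892 (without NTS-R replicate 1) to 1.241 in NTS-R against NS-R. The T cell list in NS-R against WTS-R turned by camera direction, with medians of 0.135 (without NS-R replicate 3) to 0.935 with 1 library left out, -0.074 with sex as a covariate and 0.156 in male libraries; adipocyte identity there had 0.028 with sex. With the clock gene level as a covariate the clock list had -0.304 in TS-R against WTS-R and -0.131 in NTS-R against NS-R, which the covariate brings about by construction. In NS-R against WTS-R, Ifit1 ran from -2.774 to 0.397 (without WTS-R replicate 1) and Cd3e was -0.474 with only the 2 groups compared. In NTS-R against NS-R, Nlrp3 was 0.084 with sex, Ighm ran from -0.339 to 1.73 and Gbp2 from -0.449 to 2.352, each lowest without NTS-R replicate 1. The cause was not tested. The limit that 3 counts set ran from 0.081 to 0.211 CPM, which leaves folds of weak genes such as Nlrp3 uncertain.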

Other observations

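The values in this part were chosen after the results were seen, and no test was made on them. Interferon response genes were high in 1 library each of WTS-R and NTS-R. The list level was 7.19 in WTS-R replicate 1 and 6.81 in NTS-R replicate 1, and between 3.76 and 5.33 in the other 11 libraries. The guanylate-binding gene Gbp2 was at 494 and 625 CPM in these libraries and between 39.0 and 173 CPM in the others.

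The scavenger receptor gene Marco, expressed by marginal zone and sinus macrophages, was at 2.65, 105, 161 and 193 CPM in TS-R. Mitochondrially encoded transcripts made up 6.11% of counts in TS-R replicate 1, 22.7%, 15.3% and 22.5% in TS-R replicates 2 to 4, and 36.7% in NS-R replicate 3. Nerve and Schwann cell genes had levels of 4.89, 4.17, 3.59 and 2.34 in TS-R and of 2.27, 2.30 and 2.09 in NTS-R. The Y-linked gene Ddx3y was at 0.0341 CPM in TS-R replicate 3, under the 3-count floor.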
